A study of Mus musculus with 11 samples.

How the data were processed

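The series holds 11 mouse liver RNA libraries in 4 groups, taken from the genotype and treatment labels. Per the labels' protocols the livers were frozen in liquid nitrogen, libraries were made with a stranded total RNA kit and sequenced on an Illumina HiSeq instrument. The design text also speaks of capped RNA, and which applies was not settled. Per the submitters' processing notes Bowtie, DESeq2, mm10 and GRCm38 were used, with no versions. Read length, trimming and the handling of reads with several matches were not given in the sources used here.

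Per the file headers and the column descriptions, the authors deposited 1 table with raw counts per gene and library, made with the USeq tools. An alignment was counted for a gene it overlapped by at least 1 base and a read pair was counted once, so reads in overlapping genes can be counted for each of them. Whether strand was used in counting was not given, so a gene and its antisense partner may share reads. Of the genes named here, Glul, Teddm2, Mir8114, Cdc20, Prc1, Per3, Usp2, Ciart, Cry2, Vcam1, Rhbg, Hamp2, Chka, Eln, Ehhadh, Afp, Timp1, Hmgb1, Cyp7b1, Cyp2a4, Cyp2a22, Gbp7, Il18, Apoa4 and Ddx3y overlap another gene of the table. The counts over named genes and over lists include 1 gene that is not reported here. The authors' FPKM values, deposited in the same table, are the counts scaled by gene length and by library total. Their denominators exceeded the table totals by 0.0663% to 0.117%, and they were used only for that check. The authors' deposited log2 ratios and adjusted p scores (-10 times the log10 of a DESeq2 adjusted p) were copied for comparison, with the sign turned so that positive means higher after CCl4 or in the knockout. How their model was built was not given. Other columns hold gene lengths in bases and coordinates on mm10.

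The table held 19207 genes, and another list of the authors named 30438 genes as under 10 counts and 26 as above 50000 counts, by identifier only. The 26 include Alb, Apoa1, Apoe, Fga and Saa1, so these abundant transcripts were not analysed here. In the table itself 30 genes exceeded 50000 counts in some library and 993 had no count of 10 or more, so the rule behind that list is not simply the count in a library. The symbol was blank for 2096 genes, of which 2069 were named from a reference table by Ensembl identifier.

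The counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, without robust estimation, after TMM scaling. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 16866 and removed 2341. All 11 libraries entered 1 fit of 4 group means, so that all groups share 1 estimate of each gene's spread. There were 5 contrasts, CCl4 against oil in each genotype, knockout against wild type in each treatment, and their interaction. A gene was called at an adjusted p below 0.05 (Benjamini-Hochberg over all tested genes). The standard error of a log2 fold change was its size over the square root of the test's F statistic. CPM values are counts scaled to the TMM-adjusted library size. No replicate number occurs in more than 1 group, so no libraries were paired, and no libraries were found to be duplicates of each other.

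Before the data were examined, 54 lists of genes of liver cell types, pathways, other tissues, sex and time of day were written from textbook knowledge. Of 1248 members 1138 were in the table, and 52 lists with at least 5 tested members were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, correlation between genes preset to 0.01), with an estimated correlation, and with fry. A list count is given over all genes tested and adjusted over the list alone. Also fixed beforehand was the rule for naming genes. It takes Hmgb1, Hmgb2 and Hmgb3, 11 further fixed genes (Col1a1, Acta2, Timp1, Cyp2e1, Cyp7a1, Mki67, Cdkn1a, Alb, Adgre1, H19 and Afp, where tested), the 5 largest rises and falls among called genes whose groups do not overlap and whose mean is at least 1 CPM (gene models known only by number and pseudogenes aside), the 4 best members of up to 8 called lists, the 2 best called members of lists of other tissues, sex and time of day, and 5 genes called in both genotype comparisons. A fold against a group with 0 reads was set against a floor of 3 counts over the group. No fold is given for a gene with 1 to 3 reads in a group.

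The alternatives fixed beforehand were other scalings (RLE, upper quartile), no filter and a stricter one (mean of at least 5 CPM), removal of the 50 most abundant and the mitochondrial genes, DESeq2 1.42.0, limma-voom, only the groups compared, each library left out, and both E-numbered KO_CCL4 libraries left out. Where leaving out a KO_Oil library or both E-numbered libraries left 1, that library was assumed to vary like the other groups. Added after seeing the data, each in a single version, were an offset for GC content and transcript length (a spline with 5 degrees of freedom, fitted on genes above a mean log2 CPM of 3), the removal of WT_Oil 1 and WT_CCL4 5 together, and a clock score of each library as a covariate. The score is the mean log2 CPM of day-phase less night-phase clock genes, and the phases were assigned after the values were seen. It was 3.69 and 3.61 in the KO_Oil libraries and at most 2.07 in any other. With this covariate, comparisons that take in KO_Oil therefore cannot part genotype or CCl4 from clock phase. The GC correction also removes trends that follow the groups.

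The tests were tried on simulated counts with the mean and spread of each real gene and the real library sizes over 16866 genes, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of weaker genes was not tried. The numbers recovered were 44 and 87 for CCl4 in wild type, 27 and 80 for CCl4 in knockout, 25 and 88 for the genotypes after oil, 40 and 91 after CCl4, and 2 and 57 for the interaction, with 15, 8, 2, 9 and 4 false calls. A shifted list was called and none of the others, and a simulated GC trend in a library (rho 0.565) fell to 0.00179 after correction. The genes were simulated independently of each other, and the shifted list passed with an estimated correlation too (camera adjusted p = 0.000151). This trial therefore does not bear on the preset correlation in the real libraries, where genes can vary together. Depth sets the lower limit of detection, and 3 counts correspond to 0.189 CPM in the deepest library and 0.431 CPM in the shallowest. Such floors cover counting error only.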

Results

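RNA of 11 mouse liver samples was sequenced to compare the livers of wild-type and Hmgb2-/- (knockout) C57BL/6 mice after oil or after carbon tetrachloride (CCl4). CCl4 is a solvent that hepatocytes around the central vein turn into a toxic radical, mainly through the cytochrome P450 enzyme Cyp2e1, and oil is its usual carrier. Hmgb2 encodes a chromatin protein of the high-mobility group box family. There were 3 libraries of wild-type liver after oil (WT_Oil 1, 2 and 3), 3 of wild-type liver after CCl4 (WT_CCL4 4, 5 and 6), 2 of knockout liver after oil (KO_Oil 11 and 12) and 3 of knockout liver after CCl4 (KO_CCL4 24, 25 and 15). The sex of the mice, the dose and number of CCl4 treatments and the hour of collection were not given in the sources used here. The labels do not say that every library came from its own mouse, so the p-values measure the spread between these samples, which may be technical.

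Between 7306082 counts (KO_Oil 11) and 14116886 counts (WT_CCL4 4) fell on the genes of the deposited table, and the KO_Oil libraries were the shallowest of the 11. From 18407 to 19061 genes had at least 1 count in a library, and mitochondrial genes took 1.23% to 2.19% of the counts, with 2.19% and 2.09% in the KO_Oil libraries against 1.39% to 1.60% in the WT_Oil libraries. These shares leave out mt-Co1, mt-Rnr1 and mt-Rnr2, which the authors listed apart by identifier only. On the first principal component, which held 49.0% of the variance of the 500 most variable genes, the oil libraries lay between -29.3 and -13.9 and the CCl4 libraries between -0.597 and 37.5. WT_CCL4 5 stood at 18.8 on that axis, while WT_CCL4 4 and 6 stood at 35.4 and 37.5. KO_CCL4 15 stood at 2.95 on the second component, while KO_CCL4 24 and 25, whose titles carry the letter E where all others carry S, stood at -10.5 and -19.4. Deviations of log2 CPM (counts scaled to library size) from the mean of the group's other libraries followed the GC content of the genes most closely in WT_Oil 1 (Spearman's rho 0.633 across genes). They ran the same way in WT_CCL4 5 (0.395), and the opposite way in WT_Oil 2 and 3 (-0.537 and -0.501) and WT_CCL4 4 (-0.478). A library that stands apart turns the values of the others in its group the opposite way. Genes are not independent replicates in these correlations.

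**Figure D1:**
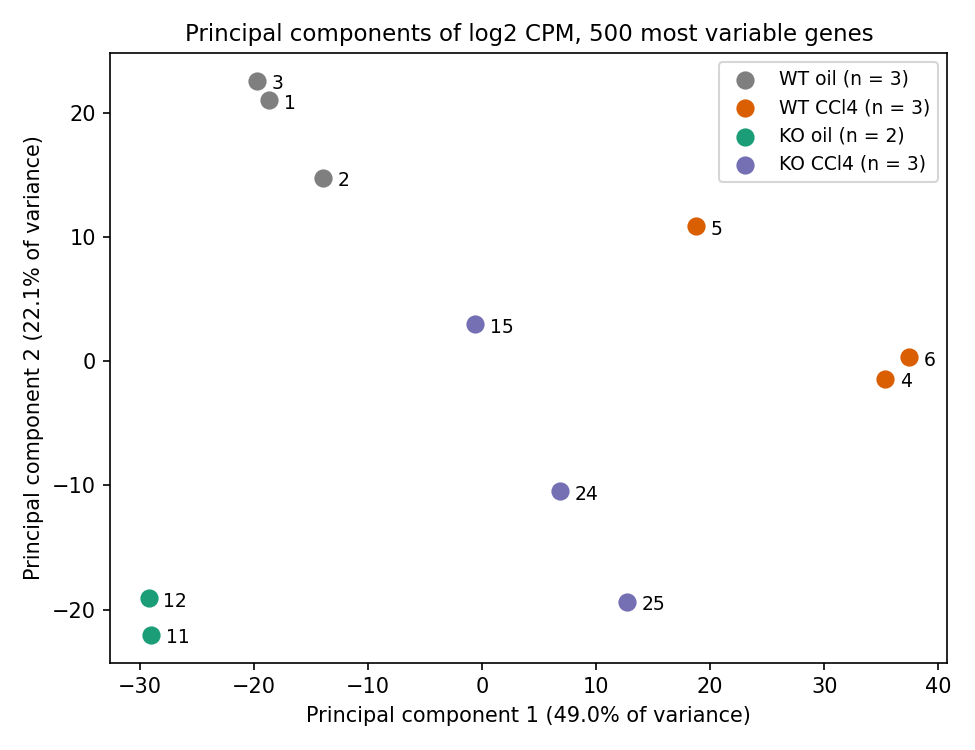
Principal components 1 (horizontal, 49.0% of variance) and 2 (vertical, 22.1%) of log2 CPM over the 500 most variable genes, in units of component score. Each point is 1 library with its replicate number, coloured by group, and CCl4 libraries lie to the right of the oil libraries of the same genotype.

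Hmgb2 (ENSMUSG00000054717, chromosome 8, 57511906 to 57515999 on the plus strand of mm10) had 1.93 to 7.42 CPM in the 6 wild-type libraries and 0 to 0.951 CPM in the 5 knockout libraries, so all knockout libraries lay below all wild-type libraries. Its mean was 2.18 ± 0.39 CPM (SD, n = 3) in wild-type liver after oil and 5.75 ± 2.29 CPM (n = 3) after CCl4, a log2 fold change of 1.40 that did not pass the test (edgeR quasi-likelihood, adjusted p = 0.0712). In knockout liver it had 0.476 ± 0.673 CPM (n = 2) after oil and 0.40 ± 0.013 CPM (n = 3) after CCl4. KO_Oil 11 had 0 reads of Hmgb2, which allows up to 0.431 CPM, and the other knockout libraries had 4 to 7 reads. Hmgb2 fell in knockout against wild-type liver after CCl4 by 3.81 on the log2 scale (SE 0.55, adjusted p = 0.0112), a call lost without WT_CCL4 4, WT_CCL4 6 or KO_CCL4 24, with an adjusted p of up to 0.0838. After oil the difference was -2.14 (SE 0.72, adjusted p = 0.115). In the authors' deposited table Hmgb2 passed both for CCl4 in wild type and for the genotypes after oil (DESeq2 adjusted p = 0.0038 and 0.0311). Which part of the gene the knockout removes was not given in the sources used here. The related genes Hmgb1 and Hmgb3 passed in no comparison, with log2 fold changes between 2 groups from -0.17 to 0.30 and from -0.11 to 0.13.

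The first question was how wild-type liver responds to CCl4. Genes of the extracellular matrix, of mitosis and of infiltrating macrophages rose together. Of 29 tested matrix genes 25 rose and none fell (27 when adjusted over the list alone), with a median log2 fold change of 2.38. The gelatinase gene Mmp2 (ENSMUSG00000031740, chromosome 8, 92827290 to 92853420, plus strand) rose 8.64-fold, from 4.25 ± 0.95 to 36.5 ± 6.33 CPM (SD, n = 3 each, adjusted p = 4.07e-05). The collagen gene Col1a1 (chromosome 11, 94936223 to 94953042, plus strand) rose from 7.51 ± 5.24 to 297 ± 191 CPM, Col6a1 rose 5.45-fold, and Lum, which encodes the proteoglycan lumican, rose 8.08-fold. Acta2 and Timp1, a smooth muscle actin and a metalloprotease inhibitor often read as fibrosis markers, had log2 fold changes of 1.31 and 0.81 that did not pass (adjusted p = 0.129 and 0.520).

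Cell division genes rose in 24 of 30 cases (28 adjusted over the list alone), with a median log2 fold change of 2.82. Mki67, a marker of cycling cells, rose 15.6-fold from 3.16 ± 1.0 to 49.9 ± 37.9 CPM, and WT_CCL4 5 had 10.6 CPM beside 86.2 and 52.9 CPM in WT_CCL4 4 and 6. Cdc20, an activator of the anaphase-promoting complex, rose 22.1-fold, the spindle gene Prc1 13.6-fold, and the cyclin gene Ccnb2 19.7-fold, while the mitotic kinase gene Plk1 rose by 3.81 on the log2 scale. Of 30 tested DNA replication genes 7 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.90. The helicase genes Mcm5 and Mcm6 rose 6.51-fold and 4.36-fold and Mcm10 fell by 0.84 on the log2 scale. These 3 calls were lost without WT_CCL4 4 or 6 and without WT_Oil 2, and also without WT_Oil 3 (Mcm5 and Mcm6) or WT_Oil 1 (Mcm10), with an adjusted p of up to 0.109, 0.0986 and 0.124. Afp, a gene of fetal liver, rose 9.98-fold, a call lost without WT_Oil 3 (adjusted p = 0.0518).

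Of 22 tested genes of monocyte-derived macrophages 20 rose (20 adjusted over the list alone), with a median log2 fold change of 1.65. Gpnmb, a gene of lipid-laden macrophages, rose 45.6-fold from 3.57 ± 3.97 to 172 ± 110 CPM, and Lgals3, which encodes galectin-3, rose 7.57-fold from a mean of 7.04 to 53.6 CPM (log2 SE 0.41). Clec7a, a receptor for fungal glucans, rose 4.90-fold. Of 18 tested Kupffer cell genes, those of the resident macrophages, 4 rose (10 adjusted over the list alone), with a median of 0.67, and the macrophage gene Adgre1 had a log2 fold change of 0.93 that did not pass (adjusted p = 0.0937). Of 13 tested B and plasma cell genes 8 rose (10 adjusted over the list alone), among them the B cell surface gene Ms4a1, 5.50-fold. Of 24 tested stellate cell genes 10 rose and 1 fell (15 and 1 adjusted over the list alone), and of 24 endothelial genes 3 rose (3 adjusted over the list alone), with medians of 1.02 and 0.27.

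Sex-biased and pericentral hepatocyte genes changed as well. Of 19 tested genes known as higher in male liver 8 fell and none rose (16 adjusted over the list alone), with a median of -1.40. Mup21, which encodes a major urinary protein, fell by 3.31 on the log2 scale, from 187 ± 43.6 to 18.8 ± 7.89 CPM (n = 3 each, adjusted p = 0.000437), and Mup15 went from 145 ± 37.2 to 0.0791 ± 0.0884 CPM. Mup genes are near-identical copies among which reads can be split, so the value of any single copy is uncertain. The steroid hydroxylase gene Cyp7b1 fell by 2.65 and the fatty acid elongase gene Elovl3 by 2.71. Of 18 tested genes known as higher in female liver 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 0.00645, adjusted p = 0.216 with an estimated correlation), among them Cyp2a4, 7.95-fold. Of 25 tested pericentral hepatocyte genes 8 fell and 1 rose (11 and 2 adjusted over the list alone), with a median of -0.53, and Cyp2e1 fell by 1.41 from 10168 ± 1299 to 3817 ± 1435 CPM (adjusted p = 0.0135). The Cyp2e1 call was lost without WT_Oil 3, WT_CCL4 4 or WT_CCL4 6 (adjusted p up to 0.0845). The periportal list had a median of -0.11 and 1 rise among 22 genes, the list of complement and coagulation a median of -0.14 and 1 fall among 33, and the list of hepatocyte secreted proteins a median of -0.06 and 0 of 14 genes called by edgeR (0 adjusted over the list alone), and camera called none of these 3. Heat shock genes fell in 4 of 18 cases (6 adjusted over the list alone), and the chaperone gene Hspb1 fell by 1.72. Immediate early genes rose in 10 of 25 (15 adjusted over the list alone), with the transcription factor gene Egr1 6.97-fold higher.

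In all 1431 of 16866 tested genes passed for wild-type liver, 1177 higher and 254 lower after CCl4, and 940 and 136 of them changed at least 2-fold. A competitive test (camera, preset correlation between genes) called 28 of 52 lists, with adjusted p = 7.61e-24 for the matrix list, 1.28e-17 for mitosis, 2.36e-16 for macrophages, 3.27e-12 for male-biased genes and 7.40e-08 for B and plasma cells. None of the 28 passed with an estimated correlation, where these 5 lists had adjusted p = 0.216, 0.216, 0.216, 0.0756 and 0.115. In the table that the authors deposited, 1868 genes passed for this comparison, of which 1297 are among the 1431. The count depended on single libraries: it was 695 without WT_Oil 2, 542 without WT_Oil 3, 532 without WT_CCL4 4, 479 without WT_CCL4 6 and 2268 without WT_CCL4 5, while 37 of 52 named calls held whichever of the 6 libraries was left out.

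**Figure D2:**
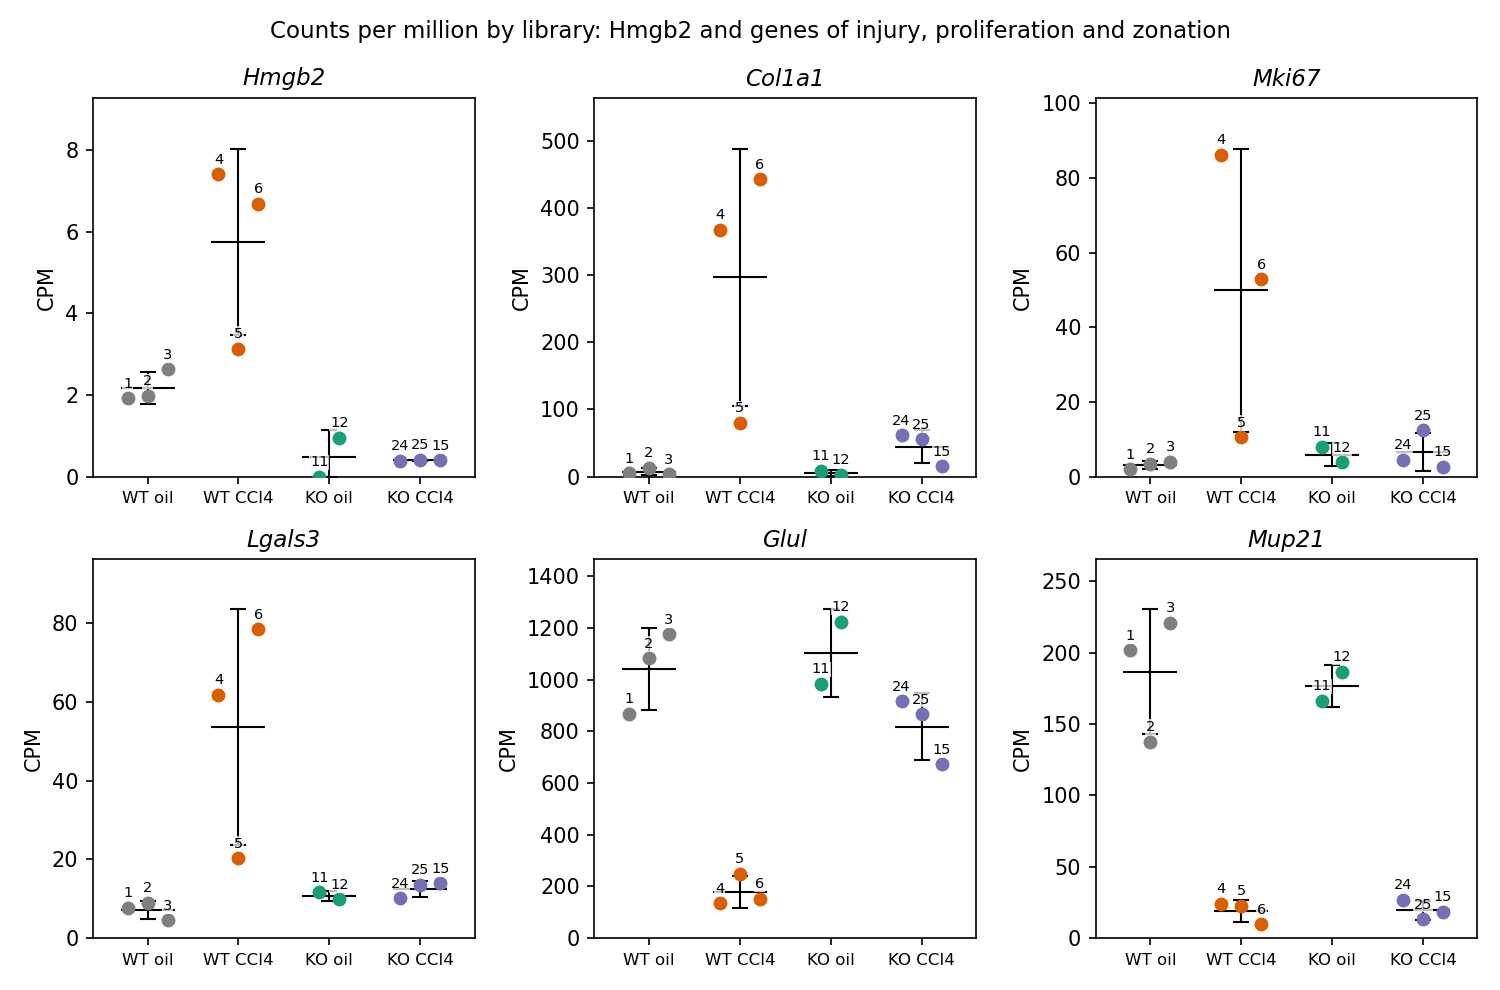
CPM (vertical, linear scale) of Hmgb2, Col1a1, Mki67, Lgals3, Glul and Mup21 in each library, by group (horizontal). Points are libraries with their replicate numbers, and bars are the group mean ± SD (drawn down to 0 at most). Glul lay between 672 and 916 CPM in the KO_CCL4 libraries, between 135 and 249 CPM in the WT_CCL4 libraries and between 867 and 1224 CPM in the oil libraries.

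The second question was how liver without Hmgb2 responds to CCl4. By camera with a preset correlation the matrix list was higher and the male-biased list lower, as in wild-type liver, with fewer genes called. Of 29 tested matrix genes 3 rose and none fell (24 adjusted over the list alone), with a median log2 fold change of 1.58 (camera adjusted p = 7.26e-19, adjusted p = 0.295 with an estimated correlation). These were Mmp2, which rose 5.38-fold from 3.07 ± 0.08 (n = 2) to 16.6 ± 2.52 CPM (n = 3, adjusted p = 0.00196), the thrombospondin gene Thbs2, 5.06-fold, and Col6a1, 2.94-fold. Col1a1 went from 5.74 ± 4.27 to 44.5 ± 24.9 CPM, a log2 fold change of 2.96 that did not pass (SE 0.86, adjusted p = 0.161). It passed in the authors' deposited table (log2 ratio 2.01, DESeq2 adjusted p = 0.0323). Of 19 tested male-biased genes 5 fell (10 adjusted over the list alone), with a median of -1.17 (adjusted p = 0.0707 with an estimated correlation). Mup21 fell by 3.19 from 176 ± 14.5 to 19.4 ± 6.82 CPM. Not all Mup copies followed, as Mup12 had 236 CPM in KO_CCL4 15 beside 137 and 145 CPM in the KO_Oil libraries, and 8.51 and 2.72 CPM in KO_CCL4 24 and 25. Beside the matrix genes, a list of adipose and mesothelium genes was called higher by camera (13 tested, 1 rose, 7 adjusted over the list alone, median 1.5, adjusted p = 8.89e-06, adjusted p = 0.295 with an estimated correlation). Its members Gpm6a, Wt1 and Upk1b went from 1.97 ± 0.87, 0.706 ± 0.422 and 0.355 ± 0.310 CPM to 6.14 ± 0.98, 2.76 ± 0.51 and 2.09 ± 0.12 CPM and did not pass singly (adjusted p = 0.0695, 0.156 and 0.161). Whether tissue of another kind adds to the matrix genes was not tested.

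Lists of cell division and of infiltrating macrophages were not called in knockout liver. Mki67 had 5.92 ± 2.99 CPM after oil and 6.57 ± 5.17 CPM after CCl4, a log2 fold change of 0.18 (SE 0.80, adjusted p = 0.963). The mitosis and cell cycle list had a median of 0.52 and 0 of 30 calls by edgeR (0 also adjusted over the list alone), and the macrophage list a median of 0.28 and 0 of 22 calls (1 higher adjusted over the list alone). With a clock score of each library as a covariate the mitosis and cell cycle list had a median of 2.64 and was called by camera, still with 0 of 30 genes. That score was far higher in the KO_Oil libraries than in any other, so this fit cannot part CCl4 from clock phase. The Kupffer cell list shifted lower (median -0.47, camera adjusted p = 7.75e-06, adjusted p = 0.352 with an estimated correlation) with 0 of 18 genes called and 3 lower when adjusted over the list alone, and with the clock covariate its median was 0.56 and it was not called.

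Single genes of metabolism and of the clock also passed in knockout liver. G6pc, which encodes the glucose-releasing step of gluconeogenesis, rose 9.18-fold from 66.3 ± 25.6 to 608 ± 230 CPM. Elovl5, which elongates fatty acids, rose 2.53-fold. Both calls were lost without KO_Oil 11 or 12, with an adjusted p of up to 0.223 and 0.315. Of 25 clock genes 2 rose and 3 fell (4 and 12 adjusted over the list alone, median -0.48, adjusted p = 0.260 with an estimated correlation), and the list was not called with the clock covariate. The deubiquitinase gene Usp2 fell by 2.13 and Ciart, a repressor in the clock, by 1.86, while Npas2, a partner of Bmal1, had 1.81 ± 0.90 CPM after CCl4 and 0 reads in both KO_Oil libraries, so it was at least 8.65-fold higher (floor of 3 counts over the group). The female-biased genes Cyp2a22 and Cyp2b9, members of cytochrome P450 families with similar copies, rose, Cyp2a22 13.5-fold and Cyp2b9 from 0.14 to 20.9 ± 7.46 CPM.

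In all 110 of 16866 genes passed in knockout liver, 56 higher and 54 lower, and 27 lists were called by camera, 0 of them with an estimated correlation. The authors' calls in the deposited table number 331, of which 99 are among the 110. The count was 9 without KO_Oil 11 (0 higher, 9 lower), 46 without KO_Oil 12 (5 higher, 41 lower), 36 without KO_CCL4 24 and 374 without KO_CCL4 15, and 4 of 21 named calls (Mup15, Mup17, Mup19 and Mup21) held whichever library was left out. The other 17 were all lost without KO_Oil 11, with an adjusted p from 0.050 (Mmp2) to 0.450 (Mup9), and most of them also without KO_Oil 12 or KO_CCL4 24.

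The third question was how the genotypes differed without injury. Knockout liver after oil had lower fatty acid oxidation genes and shifted clock genes. Of 29 tested genes of fatty acid oxidation and other targets of the nuclear receptor PPARA 14 fell and none rose (23 adjusted over the list alone), with a median log2 fold change of -1.36. Ehhadh (ENSMUSG00000022853, chromosome 16, 21761286 to 21787844, minus strand), an enzyme of peroxisomal beta-oxidation, was 10.1-fold lower, at 250 ± 76.0 (n = 2) against 2533 ± 611 CPM (n = 3, adjusted p = 0.0171). The fasting hormone gene Fgf21 fell by 5.83. Of 25 clock genes 14 rose and 2 fell (17 and 5 adjusted over the list alone). Per3 (ENSMUSG00000028957, chromosome 4, 151003651 to 151044665, minus strand) rose 12.9-fold, from 7.29 ± 1.30 to 95.1 ± 2.99 CPM (adjusted p = 0.00253), Usp2 rose 5.70-fold, Ciart 6.93-fold and Cry2 2.17-fold, and Npas2 was at least 12.1-fold lower (2.53 ± 0.83 CPM against 0 reads in 2 libraries).

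By camera with a preset correlation the lists of heat shock, cholesterol synthesis and glucocorticoid targets also differed after oil. None of them passed with an estimated correlation, and a part of their genes passed singly. Of 18 tested heat shock genes 6 fell (11 adjusted over the list alone, median -0.80), with Hspa1b at 1.05 ± 0.06 against 37.9 ± 21.8 CPM. Of 25 cholesterol synthesis genes 4 rose (12 adjusted over the list alone, median 1.02), Msmo1 4.85-fold, Insig1 4.43-fold, Idi1 6.24-fold and Stard4 3.85-fold. Insig1 encodes a brake on the pathway and Stard4 a sterol carrier. Msmo1 lies within 10 Mb of Hmgb2 on chromosome 8. With a clock score of each library as a covariate the median of the cholesterol synthesis list was -1.51 and the list was called lower, and these 4 genes turned direction. Of 16 glucocorticoid targets 5 fell (8 lower and 1 higher adjusted over the list alone), with the transcription factor gene Zbtb16 at 14.1 ± 4.09 against 56.7 ± 12.3 CPM, and this list was not called with the clock covariate. The cell cycle inhibitor gene Cdkn1a, a target of p53, had 12.7 ± 7.46 CPM in wild-type liver and 1 read in the 2 knockout libraries together. The non-coding RNA gene Vaultrc5 rose 14.6-fold and the lectin gene Clec2h 19.3-fold, with 641 and 334 CPM and 12.8 and 37.4 CPM in KO_Oil 11 and 12.

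By camera with a preset correlation 7 immune gene lists were higher in knockout liver after oil, and none of them passed with an estimated correlation. Of 32 tested interferon response genes 5 rose (12 higher and 2 lower adjusted over the list alone, median 0.80), of 19 chemokine and cytokine genes 2 (6, median 0.99), of 16 T and NK cell genes 2 (5, median 1.46) and of 13 B and plasma cell genes 2 (8 higher and 1 lower, median 1.09). The Kupffer cell list had a median of 0.55 with 1 rise among 18 genes, the macrophage list a median of 0.60 with 1 rise among 22, and the dendritic cell list a median of 0.97 with none among 16. Ms4a1 rose 3.92-fold, and the interferon-induced genes Cxcl9 and Gbp7 had 41.7 ± 32 and 56.0 ± 34.1 CPM in the 2 knockout libraries against 6.98 ± 1.05 and 11.7 ± 3.48 CPM. Camera called all 7 lists, with an adjusted p from 2.01e-05 (T and NK cells) to 0.0348 (macrophages), and from 0.225 (B and plasma cells) to 0.774 (macrophages) with an estimated correlation. The macrophage call was lost without WT_Oil 3 or KO_Oil 11, with the stricter filter and after the GC and length correction, and the dendritic cell call without KO_Oil 12. With the clock score as a covariate 6 of these medians were negative, with the macrophage, dendritic cell and interferon lists called lower, and that of B and plasma cells was 0.52 and not called.

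In all 694 genes passed for knockout against wild-type liver after oil, 370 higher and 324 lower, and 22 lists were called by camera. Camera gave adjusted p = 6.29e-17 for fatty acid oxidation, 2.01e-05 for the clock, 2.13e-06 for heat shock, 7.09e-06 for cholesterol synthesis and 0.000135 for glucocorticoid targets, and adjusted p = 0.332, 0.219, 0.225, 0.737 and 0.624 with an estimated correlation. The authors' calls in the deposited table number 1048, of which 579 are among the 694. Among the genes tested within 10 Mb of Hmgb2, 3 of 49 were called, Msmo1 among them (6.12%, against 4.11% elsewhere, two-sided Fisher's exact test p = 0.455). The count was 357 without WT_Oil 2, 130 without WT_Oil 3, 17 without KO_Oil 11 (13 higher, 4 lower) and 149 without KO_Oil 12 (109 higher, 40 lower), and it was 0 by edgeR with a clock score of each library as a covariate (without the covariate 3368 genes were at an unadjusted p below 0.05, and DESeq2 called 1297). With that covariate the median of the fatty acid oxidation list was 0.32. The score separates the KO_Oil from the WT_Oil libraries, so this fit cannot part genotype from clock phase. Per3, Usp2, Ciart and Gm4956 held whichever of the 5 libraries was left out, while each of the other 41 named calls was lost without KO_Oil 11 or KO_Oil 12, and many also without WT_Oil 1, 2 or 3, with an adjusted p of up to 0.424 (BC023105).

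**Figure D3:**
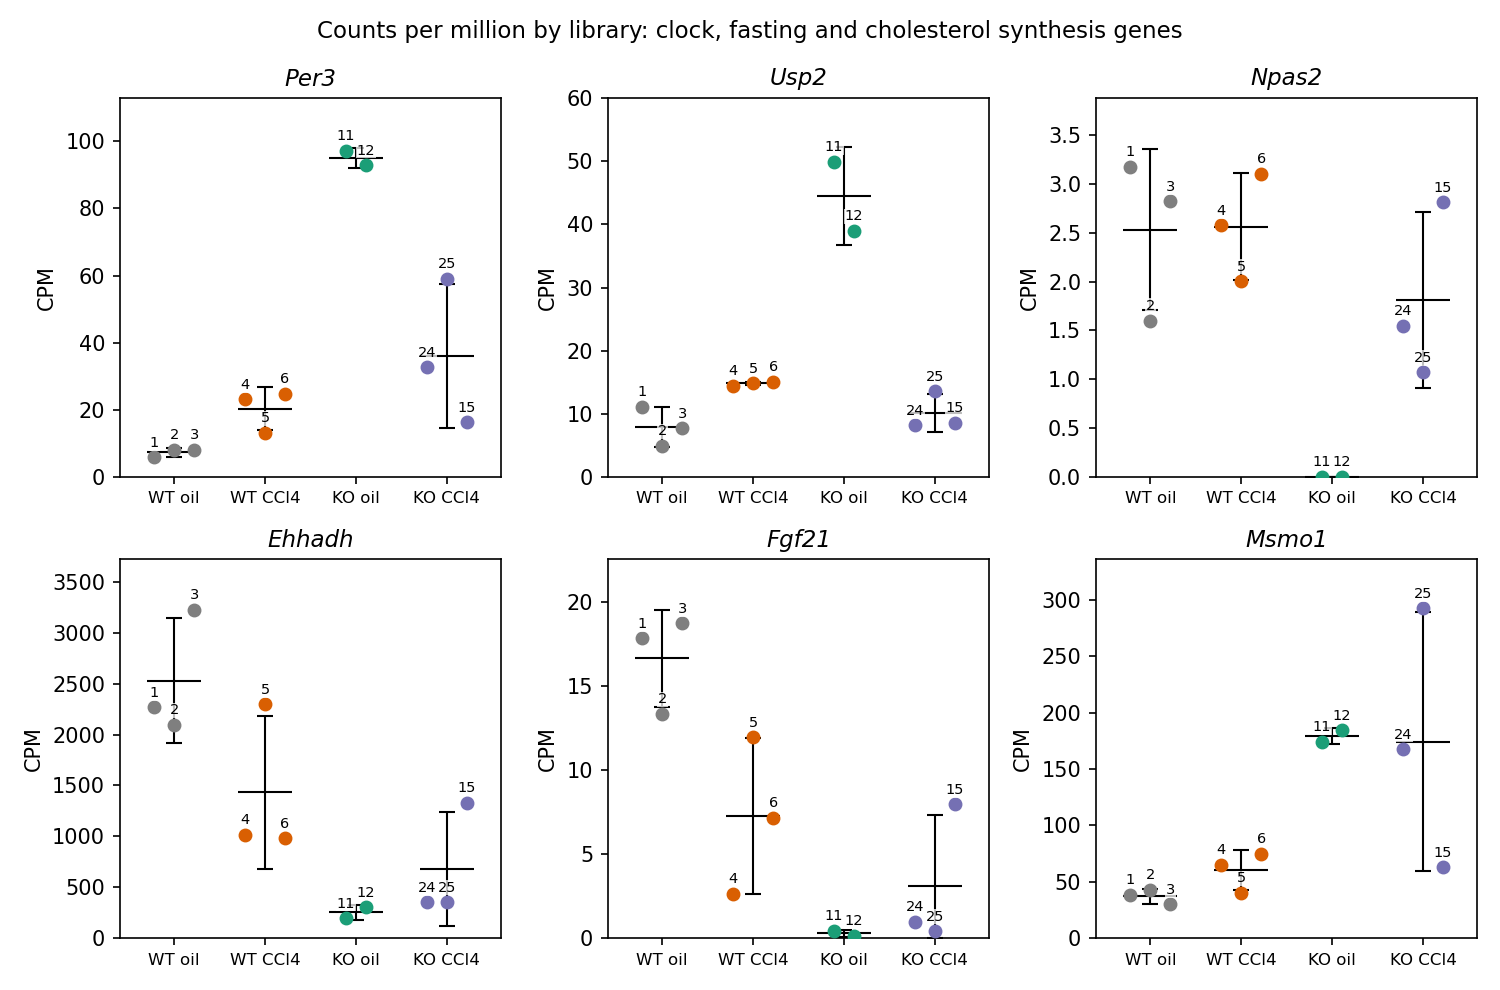
CPM (vertical, linear scale) of the clock genes Per3, Usp2 and Npas2, the fatty acid oxidation gene Ehhadh, the fasting hormone gene Fgf21 and the cholesterol synthesis gene Msmo1 in each library, by group (horizontal). Points are libraries with their replicate numbers, and bars are the group mean ± SD (drawn down to 0 at most). Per3 reached 93.0 and 97.2 CPM in the KO_Oil libraries and 16.3 to 59.0 CPM in the KO_CCL4 libraries.

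The fourth question was how the injured livers differed between genotypes. By camera with a preset correlation the lists of cell division, matrix and macrophage genes were lower in knockout liver after CCl4 and that of the pericentral hepatocyte was higher, while each had adjusted p = 0.335 with an estimated correlation and a part of their genes passed singly. Of 30 tested mitosis genes 12 fell and none rose (27 adjusted over the list alone), with a median log2 fold change of -2.41. Cdc20 was 8.07-fold lower, at 1.28 ± 0.74 against 10.6 ± 4.24 CPM (n = 3 each, adjusted p = 0.0179), Birc5, which encodes survivin, fell by 2.24, and Ccnb2 fell by 3.44. Mki67 had 6.57 ± 5.17 against 49.9 ± 37.9 CPM, a log2 fold change of -2.91 that did not pass (SE 0.66, adjusted p = 0.0556). Of 29 tested matrix genes 8 fell (23 adjusted over the list alone, median -1.08), and the elastin gene Eln fell by 1.86, the proteoglycan gene Bgn fell by 1.21 and Mmp2 fell by 1.14 (16.6 ± 2.52 against 36.5 ± 6.33 CPM). Col1a1 did not pass (log2 fold change -2.74, adjusted p = 0.0666). Mki67 and Col1a1 both passed in the authors' deposited table (DESeq2 adjusted p = 0.0016 and 0.0035).

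Of 22 tested macrophage genes 2 fell (17 adjusted over the list alone, median -0.99). Trem2, a lipid receptor gene of macrophages, fell by 2.66 and Lgals3 fell by 2.10. Of 18 Kupffer cell genes 1 fell (9 adjusted over the list alone, median -0.65), the lysosomal gene Cd68, which fell by 1.33. The endothelial list (24 tested genes) had a median of -0.08 and the T and NK cell list (16) a median of -0.01, and neither was called. The stellate cell list (24) had a median of -0.56 with 2 falls, the B and plasma cell list (13) a median of -0.33, the dendritic cell list (16) a median of -0.25, the neutrophil list (11) a median of -0.57 with 1 rise and the cholangiocyte list (12) a median of -0.10. Camera called the first 3 of these lower (adjusted p = 0.00323, 0.0120 and 0.0494), with adjusted p = 0.377, 0.335 and 0.643 with an estimated correlation. The B and plasma cell call was lost without WT_CCL4 4 or KO_CCL4 15, and the dendritic cell call without any 1 of the 6 libraries but KO_CCL4 25, with either other filter and after the GC and length correction. A list of pancreas genes was called higher by camera (adjusted p = 0.00641, adjusted p = 0.377 with an estimated correlation), with 0 of 6 tested genes called by edgeR and 3 adjusted over the list alone. These 3, Cpa1, Pnlip and Cel, had reads in KO_CCL4 24 and 25 and none in KO_CCL4 15, and the call was lost without KO_CCL4 25 (adjusted p = 0.0611), without both and without WT_Oil 1 and WT_CCL4 5 together. Whether pancreas tissue adds to other differences was not tested. Of 25 pericentral hepatocyte genes 3 rose (9 adjusted over the list alone, median 0.63). Glul (chromosome 1, 153899943 to 153909723, plus strand), the glutamine synthetase gene of the hepatocytes next to the central vein, was 4.59-fold higher, at 818 ± 129 against 178 ± 61.3 CPM (adjusted p = 0.00309). Its span overlaps Teddm2 and Mir8114, so reads counted for 1 can be counted for all 3. Rhbg, an ammonium transporter gene of the same cells, rose 7.25-fold, and Lgr5, a WNT target gene, 2.09-fold. Cyp26a1, which breaks down retinoic acid, rose by 3.70 on the log2 scale, with 63.8 ± 28.9 against 4.90 ± 3.47 CPM. Cyp2e1 had 6466 ± 2115 against 3817 ± 1435 CPM and did not pass (adjusted p = 0.219).

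None of the 25 cholesterol synthesis genes passed over all genes, and 19 were higher when adjusted over the list alone (median 1.17). The mean log2 CPM of that list was 6.55 and 7.36 in KO_CCL4 24 and 25, 5.25 in KO_CCL4 15 and 5.20 to 5.68 in the WT_CCL4 libraries, and its median log2 fold change was -0.22 without KO_CCL4 24 and 25. Of 16 glucocorticoid targets 1 fell (8 adjusted over the list alone), Zbtb16, which fell by 1.78, and the call of the list was lost without KO_CCL4 24 and 25. Genes called in both genotype comparisons, after oil and after CCl4, included the uncharacterised gene Gm4956 (14.6-fold and 6.01-fold higher) and Hamp2, a hepcidin gene (5.37-fold and 4.19-fold higher), and the choline kinase gene Chka, which fell by 1.88 and fell by 1.52. In all 14 genes were higher in both (1.14 expected of independent lists), 13 lower in both (2.88 expected) and 3 went opposite ways.

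In all 202 genes passed for knockout against wild-type liver after CCl4, 52 higher and 150 lower, and 27 lists were called by camera. Camera gave adjusted p = 1.95e-20 for mitosis, 6.56e-13 for the matrix, 4.63e-11 for macrophages, 2.06e-09 for pericentral hepatocytes, 2.68e-08 for cholesterol synthesis, 3.44e-06 for glucocorticoid targets and 1.36e-05 for Kupffer cells. With an estimated correlation adjusted p = 0.397 for cholesterol synthesis and 0.335 for each of the others. Over the alternatives with lists tested, the medians ran from -3.39 to -1.97 for mitosis, -1.46 to -0.87 for the matrix and -1.31 to -0.893 for macrophages. They ran from 0.423 to 0.749 for pericentral hepatocytes, -1.01 to -0.436 for glucocorticoid targets, -0.883 to -0.462 for Kupffer cells and -0.22 to 1.53 for cholesterol synthesis. The authors' calls in the deposited table number 598, of which 181 are among the 202. The count was 18 without WT_CCL4 4 (10 higher, 8 lower), 19 without WT_CCL4 6 (12 and 7) and 14 without KO_CCL4 24 (10 and 4). It was 633 without WT_CCL4 5 (133 and 500), 171 without KO_CCL4 25 (47 and 124) and 362 without KO_CCL4 15 (192 and 170). The larger share of lower genes thus held without WT_CCL4 5 or KO_CCL4 25 and in no other of these fits. With all libraries it held with DESeq2 (253 and 470), limma-voom (34 and 70) and the GC and length correction (147 and 228). Cyp26a1, Rhbg, Glul, Zbtb16, Gm4956, Hamp2 and Chka held whichever of the 6 libraries was left out. The mitosis, matrix, macrophage and Kupffer cell genes named here and Lgr5 were lost without WT_CCL4 4, WT_CCL4 6 or KO_CCL4 24 with their sign kept (adjusted p up to 0.111 for Ccnb2, 0.118 for Mmp2, 0.157 for Trem2, 0.177 for Cd68 and 0.189 for Lgr5), Trem2, Lgals3 and Lgr5 also without KO_CCL4 25 and Cd68 without KO_CCL4 15.

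**Figure D4:**
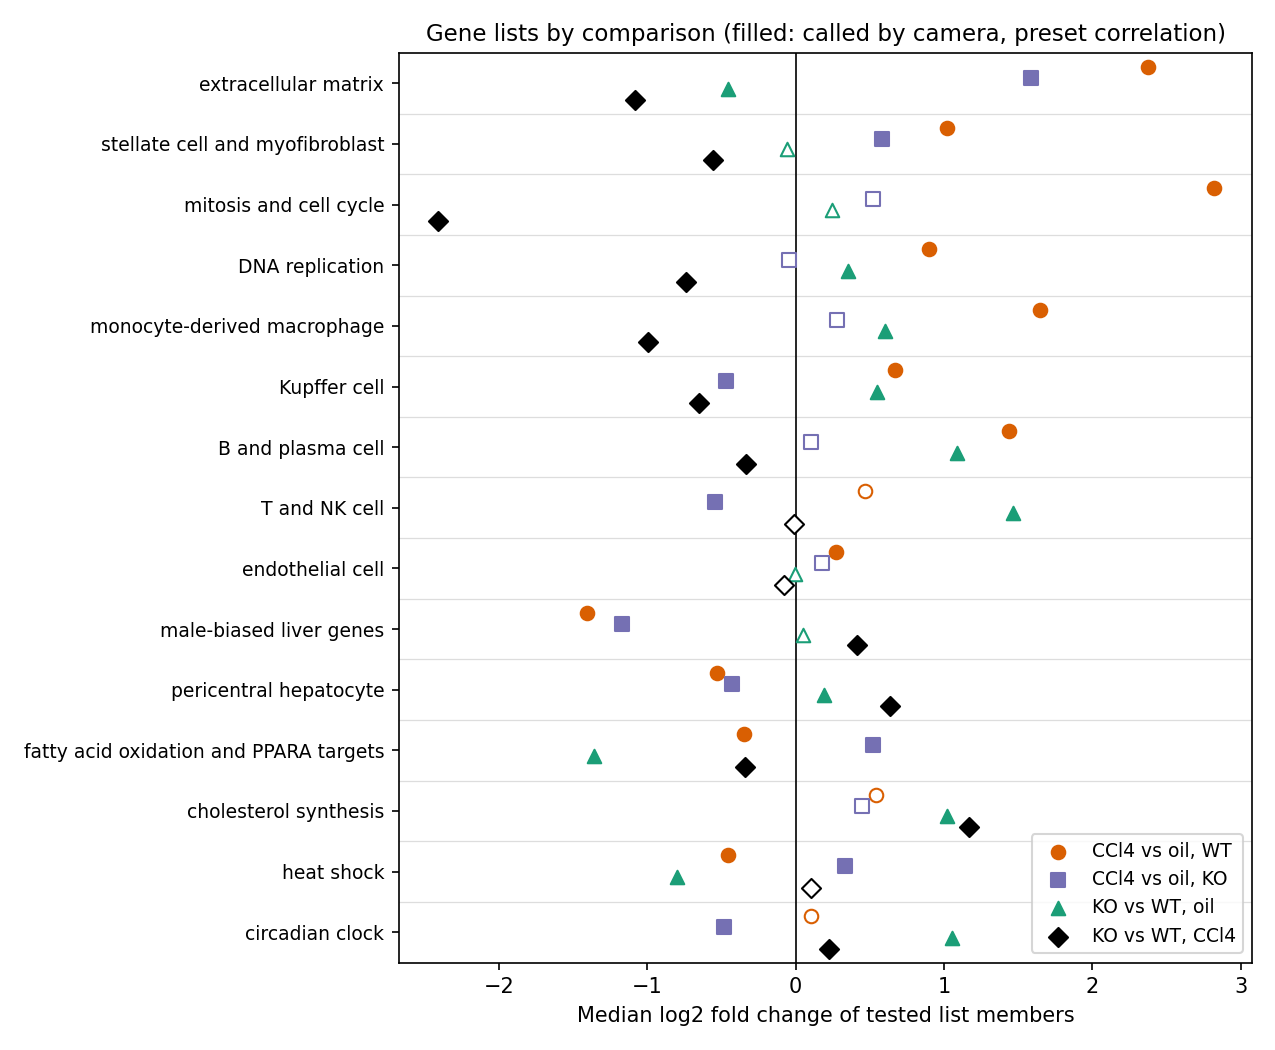
Median log2 fold change over the tested members (horizontal) of 15 gene lists (vertical) in 4 comparisons, 1 symbol each. Filled symbols are lists called by camera with a preset correlation, and no list passed with an estimated one. The mitosis list had a median of 2.82 for CCl4 in wild-type liver and -2.41 for knockout against wild-type liver after CCl4.

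The last question was whether the response to CCl4 itself differed between genotypes, which the interaction term tests. It was lower in knockout liver for Ciart, Usp2, the stress kinase gene Map2k6, the myeloid receptor gene Clec12a and the adhesion gene Vcam1, and higher for the tubulin gene Tubb2a, the Toll-like receptor gene Tlr12, Insc, Mir8114 and Elovl5. For Ciart, Usp2, Map2k6, Tubb2a, Insc and Elovl5 the genotypes differed mainly after oil, and Mir8114 followed Glul, which it overlaps. Usp2 had a log2 fold change of 0.92 in wild-type and -2.13 in knockout liver (interaction -3.05, SE 0.40, adjusted p = 0.0159), and Vcam1 of 1.60 and -0.32 (interaction -1.92, SE 0.28, adjusted p = 0.0259). After correction for GC content and length the Vcam1 interaction was -1.90 and no longer passed (adjusted p = 0.0696), and over the other alternatives its adjusted p ran from 3.67e-06 (DESeq2) to 0.867 (clock covariate). None of the mitosis, matrix or macrophage genes passed this test over all genes. Their lists were lower by camera, with medians of -2.23 (mitosis, 12 of 30 lower adjusted over the list alone), -1.57 (macrophages, 11 of 22) and -0.71 (matrix, 1 of 29), and had adjusted p = 0.377, 0.417 and 0.695 with an estimated correlation. With the clock score as a covariate the medians were -0.23, -0.26 and 0.20, and none of these 3 lists was called. The score was far higher in the KO_Oil libraries than in any other, and its slope rests mainly on the KO_CCL4 libraries. This fit therefore cannot tell whether clock phase accounts for the difference between the responses. The macrophage list had stood 0.60 higher in knockout than in wild-type liver after oil and -0.99 after CCl4, so its lower response takes in a higher start. For Mki67 the interaction was -3.79 (SE 1.1, adjusted p = 0.161), for Col1a1 -2.31 (SE 1.1, adjusted p = 0.362) and for Clec7a -1.86 (SE 0.33, adjusted p = 0.0570).

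In all 17 genes passed the interaction test by edgeR, 10 higher and 7 lower, against 2318 at an unadjusted p below 0.05 and 372 called by DESeq2. The count was 40 without WT_Oil 1, 4 without WT_Oil 2, 0 without WT_Oil 3, 6 without WT_CCL4 4, 296 without WT_CCL4 5, 4 without WT_CCL4 6, 0 without KO_Oil 11 or 12, 6 without KO_CCL4 24, 168 without KO_CCL4 25, 84 without KO_CCL4 15, 78 after the GC and length correction and 2 with the clock covariate, and none of the 10 named calls held in all of the fits with a library left out. None of the 10 passed with the clock covariate, where each kept its sign. Across all tested genes the log2 fold changes of CCl4 in the 2 genotypes, which share no library, had Pearson's r = 0.362 and Spearman's rho = 0.209. Of the 1431 genes called in wild-type liver 73.7% changed in the same direction in knockout liver, and the median ratio of the knockout to the wild-type log2 change was 0.258. These genes were chosen by their change in the same wild-type libraries, which by itself lowers this ratio. It is therefore no measure of the relative size of the knockout response. Higher in both genotypes were 23 called genes (3.91 expected of independent lists) and lower in both were 21 (0.813 expected), and 2 went opposite ways.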

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

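Of the tests in this part, those on the phase of the clock genes, on the clock scores of the knockout libraries and on other non-hepatocyte cells were chosen after the result was seen, and so were the clock covariate and the GC correction they draw on.

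The response to CCl4 differed between genotypes by the interaction term for 17 genes and, by camera with a preset correlation, for 21 lists (0 lists with an estimated correlation). The genes named by the rule were Tubb2a (2.77), Tlr12 (2.20), Insc (2.09), Mir8114 (2.08), Elovl5 (2.07), Ciart (-3.15), Usp2 (-3.05), Map2k6 (-2.72), Clec12a (-2.51) and Vcam1 (-1.92), all log2 differences between the responses. Mir8114 overlaps Glul and Teddm2 in the genome, and Teddm2 is among the 17 genes as well. Over the 11 libraries the Mir8114 counts ranked in the same order as those of Glul. They ran from 138 beside 1607 in WT_CCL4 6 to 1230 beside 14189 in WT_Oil 2. Mir8114 can therefore not be told from Glul here and is not a separate result. Ciart and Usp2 are clock genes whose difference rests largely on the KO_Oil libraries, where they were highest. By the authors' deposited log2 ratios the genotypes also differed mainly after oil for Tubb2a (-2.02, and 0.55 after CCl4), Insc (-1.65 and 0.28), Elovl5 (-2.34 and -0.33) and Map2k6 (2.14 and -0.23). They differed mainly after CCl4 for Mir8114 (0.0064 after oil and 2.01) and Vcam1 (0.47 and -1.38), and after both for Tlr12 (-1.08 and 1.05) and Clec12a (1.31 and -0.98).

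The first pattern weighed is the shift of clock and fasting genes in knockout against wild-type liver after oil. All 16 scored clock genes, of 25 tested, moved as a single shift of phase asks, but their phases were assigned after the values were seen, so this does not decide for a different hour of collection or feeding state. The clock scores were 3.69 and 3.61 in KO_Oil 11 and 12 and -0.235 to 0.557 in the wild-type libraries, and 2 knockout libraries after CCl4 lay inside that range (0.329 in KO_CCL4 24 and -0.0392 in KO_CCL4 15, beside 2.07 in KO_CCL4 25), which does not bear on the oil groups. A trend with GC content is argued against as the whole cause, since 100% of the 30 clock and fatty acid oxidation calls stayed after correction. Loss of Hmgb2 and a different hour or feeding state cannot be told apart, because either would set all KO_Oil libraries apart and no label gives the hour or the feeding state.

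The second pattern is the distance of WT_Oil 1 and WT_CCL4 5 from their groups. WT_Oil 1 was closer to WT_CCL4 5 (Spearman's rho 0.973 across genes) than to WT_Oil 2 and 3 (0.969 and 0.972), while WT_CCL4 5 was closest to WT_CCL4 6 (0.977). Their deviations correlated across 9525 genes (r = 0.461), and after correction for GC content and length the correlation was 0.286. A technical trend with GC content and another difference shared by these libraries cannot be told apart, because the correlation fell by less than the bound set for the first and by more than that set for the second. No biological explanation was tested.

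The third pattern is the lower level of mitosis and matrix genes in knockout against wild-type liver after CCl4. After the GC correction the smaller ratio of the new to the old median was 0.909 (medians -2.41 and -0.98, before -2.41 and -1.08). This argues against a GC trend as the whole cause. With the clock covariate the smaller ratio was 1.06 (-2.84 and -1.14). The clock scores of the WT_CCL4 and KO_CCL4 libraries overlapped, so this fit could change the medians only a little. The score also holds clock genes only and does not measure feeding. A different hour of collection or feeding state is therefore not decided by this fit. Fewer non-hepatocyte cells of all types are argued against by the endothelial list, whose median lay 0.918 above that of the macrophage list, beyond its interquartile range of 0.373. A difference in exposure or injury between animals, apart from genotype, stays open and untested, and it could act within a group as well, since WT_CCL4 5 had 10.6 CPM of Mki67 and 80.3 CPM of Col1a1 beside 52.9 to 86.2 and 368 to 443 CPM in WT_CCL4 6 and 4. The genotype effect is a hypothesis found and tested on the same libraries.

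For CCl4 in wild-type liver, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 1431 genes, and the highest other gave 70. For the genotypes after CCl4, 1 of the 10 splits, the real one, gave as many as 202 genes, and the highest other gave 1. With 10 splits no share under 0.05 can arise.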

How the results depend on the processing

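The GC and length correction, the removal of WT_Oil 1 and WT_CCL4 5 together and the clock covariate were chosen after seeing the data, and the other alternatives before.

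RLE scaling, upper-quartile scaling, no filter and removal of the 50 most abundant and the mitochondrial genes kept all 5 counts within 1.5 times. Under upper-quartile scaling higher calls made up 87.7% of those for CCl4 in wild type (82.3% with TMM) and 18.3% of those for the genotypes after CCl4 (25.7% with TMM).

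The stricter filter, which tests fewer genes, gave 752 for CCl4 in wild type and 103 for the genotypes after CCl4. DESeq2 gave 390 for CCl4 in knockout, 1297 for the genotypes after oil, 723 after CCl4 and 372 for the interaction, and of the edgeR calls it kept 110 of 110, 684 of 694, 202 of 202 and 17 of 17. limma-voom gave 55 for CCl4 in knockout and 104 for the genotypes after CCl4. With only the 2 groups compared, which leaves fewer samples, these were 49 and 44. Without both E-numbered KO_CCL4 libraries, which leaves 1 there that is assumed to vary like the other groups, the genotypes after CCl4 gave 39 (32 higher, 7 lower) and the interaction 257. The GC and length correction gave 1138 for the genotypes after oil, 375 after CCl4 and 78 for the interaction. Without WT_Oil 1 and WT_CCL4 5 together there were 2231 for CCl4 in wild type, 228 in knockout, 968 for the genotypes after CCl4 and 333 for the interaction. Where no reason is given, the cause was not tested.

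With the clock score as a covariate edgeR gave 643 genes for CCl4 in wild type, 15 in knockout, 0 for the genotypes after oil, 486 after CCl4 and 2 for the interaction. The score separates the KO_Oil libraries from all others, and its slope rests mainly on the spread among the KO_CCL4 libraries. The count of 0 thus cannot part genotype from clock phase. The same limit holds for every value with this covariate in a comparison that takes in KO_Oil, the interaction and the response of knockout liver included. Under this covariate 16 named genes turned direction for the genotypes after oil, namely BC023105 (-0.0501), Fgf21 (2.30), Msmo1 (-0.89), Insig1 (-1.04), Idi1 (-1.45), Stard4 (-1.23), Blnk (-0.30), Ifi44 (-0.14), Gbp7 (-0.0736), Gbp3 (-0.43), Cxcl9 (-0.45), Il18 (-0.0582), Cidec (0.13), Apoa4 (0.68), Elovl3 (0.71) and Cyp2a4 (-0.61).

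Leaving out each library in turn gave 479 to 2268 genes for CCl4 in wild type, 9 to 374 in knockout, 17 to 479 for the genotypes after oil, 14 to 633 after CCl4 and 0 to 296 for the interaction. Where this leaves 1 KO_Oil library, it is assumed to vary like the other groups. The lists called by camera went from 28 to 26 and 30 at the extremes, from 27 to 20 and 26, from 22 to 18 and 21, from 27 to 20 and 28 and from 21 to 19 and 27, in the same order. With an estimated correlation 0 lists were called in each of the 5 comparisons, while fry called 20 for CCl4 in wild type, 7 in knockout, 6 for the genotypes after oil, 3 after CCl4 and 5 for the interaction, and camera with the clock covariate called 13 for the interaction. The correlation of the 2 responses (0.362) was 0.305 with no filter, 0.462 with the stricter filter and 0.243 to 0.414 without each library. For genes near Hmgb2 the p-value without each library ranged from 0.085 to 1 after oil and from 0.392 to 1 after CCl4.

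Of 5200 values of named genes under the alternatives 4396 kept direction and side of the threshold, 565 no longer passed, 223 newly passed and 16 turned direction. No paired analysis was possible because no replicate number occurs in 2 groups. Other pseudocounts were not run. The edgeR test takes the counts as they are, while the list tests, the principal components and the library scores used a prior count of 2 only. Depth limits the KO_Oil libraries most, with 7306082 and 7506468 counts.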

Other observations

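The differences between libraries in this part were singled out after the values were seen and were not tested, while Cdkn1a and the lists of pancreas and fatty acid oxidation genes were fixed before the data were examined and tested between groups.

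The pancreatic enzyme genes Cpa1, Pnlip and Cel had 0.967, 1.26 and 1.84 CPM in KO_CCL4 24 and 1.32, 1.40 and 1.40 CPM in KO_CCL4 25. They had 0 reads in the other 9 libraries, except Cel with 0.188 CPM in WT_CCL4 6.

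Y-linked genes were present in all 11 libraries, so each held RNA of male tissue, although the sex was not given. Ddx3y had 25.8 CPM in WT_Oil 1, 36.7 in WT_CCL4 5 and 54.0 in WT_CCL4 6, against 97.4 to 138 CPM in the other 8, and Eif2s3y had 14.2, 18.7 and 25.8 CPM against 39.2 to 64.5 CPM. Kdm5d ran from 24.8 to 38.0 CPM.

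Cdkn1a had 15.5 CPM in KO_CCL4 15, 2.13 in KO_CCL4 24 and 0.989 in KO_CCL4 25. The mean log2 CPM of the list of fatty acid oxidation genes and PPARA targets was 8.22 in KO_CCL4 15, 7.19 and 6.92 in KO_CCL4 24 and 25, 6.40 and 6.86 in KO_Oil 11 and 12 and 7.86 to 8.64 in the 6 wild-type libraries.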
